A study of Mus musculus with 32 samples.

How the data were processed

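The data are 32 spatial transcriptomics libraries of mouse brain. Each library came from 1 section, 10 µm thick, cut on a cryostat from fresh frozen tissue in OCT and placed on a 10x Genomics Visium slide, an array of barcoded spots that captures the messenger RNA of the tissue above it. Sample titles give a set (prl or sub), a group (control or test) and a number. The test group is read here as the activated brains that the series text sets against controls. The labels do not say what prl and sub stand for, so both are used as labels only. Neither do they say how the circuit was activated, when the tissue was taken or which sections came from the same animal.

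The authors deposited UMI counts (unique molecular identifiers, 1 per captured transcript molecule) for each feature and spot over tissue, made with Space Ranger 2.0.1 per the file headers and mm10 per the submitters' processing notes. The deposited counts are raw: they are whole numbers, without normalization, and their totals differ between sections. The feature list holds 32285 mouse genes and 8 added features that are not mouse genes. One is named VIRUS, 2 are named Con1 and Con2, and the others carry names of reporter or tool genes (EGFP, GFP, mCherry, Chr2, cas9). The files give gene symbols and Ensembl identifiers but no coordinates. Barcode, feature and position files, per the file headers and their content, hold other values: text labels and spot positions.

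Spots with at least 500 UMIs were kept, 101559 in all, and 352 spots were left out. A section kept 2476 to 4162 spots. Depth ranged from 33.8e6 to 78.7e6 UMIs per section, with a median of 10144 to 21792 UMIs and 3838 to 5748 genes per spot, and mitochondrial transcripts took 7.05 to 11.4% of UMIs. Counting error is small at this depth for genes above a few UMIs per 1e6 (CPM). A section in which a feature had 0 UMIs can still hold up to 3 UMIs of its total. Every within-group pair of sections (116 pairs) was checked for duplicated libraries. Counts of paired sections differed by a chi-square of at least 3.99 per gene, where resampling of 1 library would give about 1.

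For whole sections, UMI counts were summed over spots and compared with edgeR 4.0.16 in R 4.3.3. The steps were TMM factors, filterByExpr (17623 genes kept) and a quasi-likelihood fit with 4 group means over all 32 sections, with contrasts for prl, for sub and for the difference between them. Benjamini-Hochberg adjusted p under 0.05 was the threshold throughout. Fold changes are log2 of test over control with the standard error of the fit, and CPM values are means ± SD over sections. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The 32 lists held 480 genes. For each section the summed CPM of 26 rapid activity-regulated genes was taken as log2 and compared by an exact two-sided permutation of the sections, with 24 delayed activity-regulated genes as a second list.

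Regions were found by clustering spots without using any group. Each spot was scaled to 10000 UMIs and logged. The 2000 most variable genes were standardized and clipped at 8, leaving out both activity lists and the Y-linked, mitochondrial and erythrocyte lists. The first 30 principal components were corrected over sections with Harmony, written in numpy 2.4.6, and a graph of 15 neighbours was split with Leiden (leidenalg 0.10.2) at resolution 1.0. This gave 39 regions, named by their 2 leading genes in control spots (1 region had no control spot and so has no name). A marker set is given where its genes led the region, and regions without one carry gene names only. Within a region, UMIs were summed per section where at least 20 spots were present. A region was tested with the same edgeR steps where at least 4 sections of each group remained, and p-values were adjusted over all gene-region pairs of a set. Leading genes of a region were not read as results of that region. Each region's share of spots was compared by exact permutation.

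Design, gene lists, marker sets, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 rising and 10 falling genes with the largest fold change among called genes with a mean of at least 10 CPM and medians that differ in the same direction. It takes 5 and 5 per region, the 4 list members with the smallest p, and always Fos, Fosb, Junb, Egr1, Npas4, Arc, Nr4a1, Bdnf and Homer1. Symbols that are only a clone or model name were passed over. Alternatives chosen then were DESeq2 1.42.0, limma-voom with section quality weights, no filter on low counts, fits of 1 set alone, all spots over tissue, region composition, depth or 1 surrogate variable (sva 3.50.0) as covariates, a block for equal numbers, 50 spots per region, coarser and finer regions (19 and 53) and leaving out each section in turn.

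Several choices were made after the data were seen. A robust version of the quasi-likelihood fit was run first and is kept as an alternative, since the planned fit is the default one. Correction of the components over sections was added because uncorrected clusters parted hippocampal regions by their response. Xist and Y-linked transcripts gave each section's sex, and a region with CA1 markers of at least 50 spots gave its level (a minimum of 20 spots was tried first). Consecutive numbers of a group were then parted into 10 runs. A new run began where the numbers broke or the sex changed, so each run is of 1 sex by definition. Only prl test sections 9 to 14 were unbroken and parted by sex alone, between 12 and 13. Each run held sections both with and without CA1. In the prl set the runs were sections 1 to 4, 9 to 10 and 13 to 14 of the control group, and 1 to 4, 9 to 12 and 13 to 14 of the test group. In the sub set they were sections 5 to 8 and 11 to 12 of the control group, and 5 to 8 and 15 to 18 of the test group. A run may be 1 animal, which the labels do not state. Residuals of sections of a run were correlated by 0.44, and by 0.564 with the level in the model. Level, sex, sections with or without CA1, sums per run, runs as a random block, and splits that keep runs whole were therefore added as alternatives.

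Pairing of equal numbers was checked on residuals of 2000 genes within each group. In the prl set, 7 of 8 numbers correlated above 0.1 across groups, with a range of -0.204 to 0.522. These sections were treated as unpaired, although number 10, which fell below 0.1, joins a control section without CA1 to a test section with it. In the sub set all 4 shared numbers did, from 0.317 to 0.401, although 2 of the 4 correlated best with their own number, and equal numbers there also share sex and level. Values with a block for the number are given beside the sub results where they end the call of a gene or list named there or move a count by over 1.5 times. Beside the prl results they are given where they end the call of a named gene. The main fits use every section without the block, as fixed at the start.

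The tests were checked on simulated data with the same depths and the dispersion of the fit. The spread particular to single genes and any structure between animals were left out. Simulated 2-fold changes were found for 89.6% of genes in whole prl sections and 85.1% in whole sub sections, and 1.5-fold changes for 64.2% and 52.2%. Counts of calls were set against 100 random splits of the sections (25 for regions). Figures were drawn with matplotlib 3.10.9, and permutations were run with scipy 1.17.1 in Python 3.11.15. Images were not used.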

Results

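Transcripts were counted in place in 32 mouse brain sections, taken from control brains and from brains after activation of a neural circuit, to find which genes change with activation. Sections fell into 4 groups: 8 prl control, 10 prl test, 6 sub control and 8 sub test sections. Each section gave 33.8e6 to 78.7e6 UMIs over 2476 to 4162 spots, with a median of 10144 to 21792 UMIs per spot. The median depth per spot was 15033 ± 2563 (SD, n = 8) in prl control and 14715 ± 1504 (SD, n = 10) in prl test sections (exact two-sided permutation p = 0.745). It was 17015 ± 3218 (SD, n = 6) in sub control and 16531 ± 3560 (SD, n = 8) in sub test sections (exact two-sided permutation p = 0.798). Prl and sub are the labels of the sections, whose meaning is not stated.

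Rapid activity-regulated genes, which neurons transcribe within minutes of firing, were higher in test than in control sections of both sets. Their summed level in prl sections was 9.82 ± 0.23 log2 CPM (SD, n = 8) in controls and 11.13 ± 0.84 (SD, n = 10) in test sections, a difference of 1.31. In this set 8 of 10 test sections lay above every control section (exact two-sided permutation p = 0.000754). In sub sections the level was 9.92 ± 0.23 (SD, n = 6) and 12.05 ± 0.35 (SD, n = 8), a difference of 2.14, and 8 of 8 test sections lay above every control section. The exact two-sided permutation p was 0.000333, the smallest that these sections allow. The runs of consecutive numbers within the prl test group stood at 12.04 (sections 1 to 4), 10.73 (sections 9 to 12) and 10.09 (sections 13 to 14), the last within the range of the control sections. Delayed activity-regulated genes, which follow over the next hours, were higher by 0.87 in prl and 1.27 in sub test sections. When sections were averaged over runs of consecutive numbers of 1 sex, the differences were 1.08 in prl and 2.20 in sub sections, but 3 against 3 and 2 against 2 runs cannot give an exact permutation p below 0.1 and 0.333, and theirs were 0.2 and 0.333. Paired by their numbers, the 4 sub pairs differed by 1.80, with an exact sign-flip permutation p = 0.125, the smallest that 4 pairs allow.

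**Figure D1:**
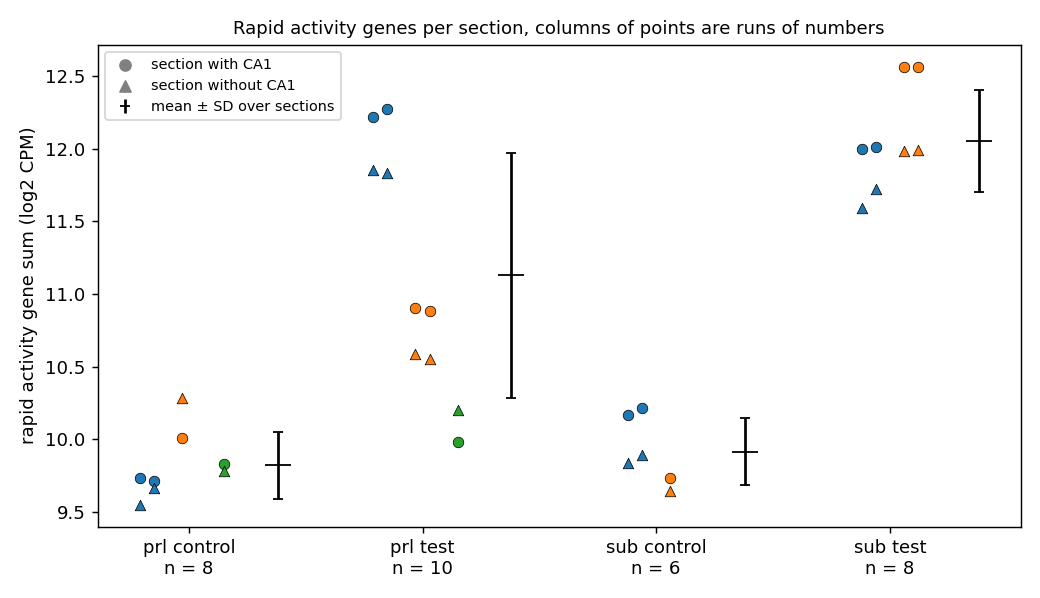
Summed level of rapid activity-regulated genes (vertical axis, log2 CPM) in each section, by group (horizontal axis). Within a group, points of 1 colour side by side are a run of consecutive numbers. Circles are sections with the CA1 region, triangles sections without it, and lines with bars are group means ± SD. Sub test sections lie between 11.6 and 12.6, above every sub control section, and prl test sections between 9.98 and 12.3, with the runs at different levels.

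In whole prl sections, transcription factors that neurons switch on when they fire were higher in test brains than in controls. Fosb rose from 7.98 ± 3.8 CPM (SD, n = 8) to 121 ± 95.8 CPM (SD, n = 10), a log2 change of 3.93 ± 0.47 (SE), and was above every control section in 10 of 10 test sections. Fos rose by 2.85 ± 0.38 and Egr1 by 1.89 ± 0.23 on the log2 scale. Fos was above every control section in 8 and Egr1 in 9 of 10 test sections. Atf3, a stress-responsive factor, rose by 4.78 ± 0.77, Npas4, which controls inhibitory synapses, by 3.90 ± 0.63, Egr2 by 3.59 ± 0.52 and Egr4 by 3.19 ± 0.43. Atf3 went from 1.45 ± 0.61 CPM (SD, n = 8) to 39.8 ± 48.8 CPM (SD, n = 10), and Npas4 from 6.51 ± 2.55 to 97.3 ± 110 CPM. Atf3, Npas4 and Egr2 were each above every control section in 8 of 10 test sections. Means of test and control runs overlapped for Atf3, Npas4, Egr2, Fos, Junb, Nr4a1 and Arc. Rises were also called for Ptgs2, a prostaglandin synthase (4.0 ± 0.63), Inhba, an activin subunit (2.56 ± 0.42), Nptx2, a secreted pentraxin that gathers glutamate receptors (2.46 ± 0.31), and Bdnf, a neurotrophin (1.81 ± 0.38). Homer1, a scaffold of the postsynaptic density, rose by 2.10 ± 0.30, Cenpa, a centromeric histone, by 2.99 ± 0.58, Junb by 1.83 ± 0.38 and Nr4a1 by 1.67 ± 0.37. Junb and Nr4a1 were above every control section in 6 and Arc in 4 of 10 test sections. Arc, a regulator of glutamate receptor turnover, rose by 1.75 ± 0.46 (adjusted p = 0.0227). Its call was lost in 4 of 18 fits that left out 1 section (prl control 1, prl control 3, prl test 1 or prl test 2), with an adjusted p of up to 0.058. Paired by number, Arc was not called either (adjusted p = 0.115, edgeR).

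The falling genes named for prl sections moved less. Arid4a, a chromatin regulator, fell by 0.42 ± 0.08 on the log2 scale, Hdhd3 by 0.36 ± 0.08, Mterf2, a mitochondrial transcription factor, by 0.35 ± 0.09 and Nol8, a nucleolar protein, by 0.34 ± 0.06. Each was below every control section in 8 of 10 test sections. Falls were also called for Sult1a1 (-0.98 ± 0.26), Sgk3 (-0.86 ± 0.25), Mgp (-0.72 ± 0.19), Zfas1 (-0.37 ± 0.10), Pdzd2 (-0.34 ± 0.09) and Dtd2 (-0.34 ± 0.10). Sult1a1, Sgk3 and Mgp were below every control section in 0 of 10 test sections, Zfas1 and Pdzd2 in 4 and Dtd2 in 6. For these 6 the call did not survive every omission of 1 section. Sult1a1 lost it without prl control 1, 2, 3 or 4 (adjusted p up to 0.0706), Mgp without prl control 1, 2 or 3 (up to 0.0974) and Zfas1 without prl control 3 or 9 (up to 0.0535). Sgk3 lost it without prl control 1, 2, 3 or 4 or prl test 1, 2, 9, 10, 11 or 12 (up to 0.119), Dtd2 without the same sections or prl control 9 (up to 0.0782), and Pdzd2 without prl control 1, 2, 3, 4 or 14 or prl test 1, 9 or 10 (up to 0.0724). Paired by number, Sgk3 (adjusted p = 0.069, edgeR), Mgp (0.086), Zfas1 (0.134) and Dtd2 (0.0917) were not called, while Sult1a1 (0.0257) and Pdzd2 (0.0108) were.

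By gene group, 21 of 26 rapid activity-regulated genes and 19 of 24 delayed ones rose in prl test sections, among the latter Rgs2, a regulator of G protein signalling (1.51 ± 0.18). Adjusted over the list alone, 25 and 21 passed. The lists stood above other genes with adjusted p = 6.86e-27 and 6.94e-21, and each gave adjusted p = 0.0535 with an estimated correlation. Of the cholesterol synthesis genes 13 of 17 rose (16 adjusted over the list alone), among them the synthesis enzymes Cyp51 (0.62 ± 0.10) and Msmo1 (0.45 ± 0.08). Heat shock and protein folding genes rose in 10 of 20 (14 adjusted over the list alone), including the chaperones Hspa8 (0.31 ± 0.06) and Dnajb5 (0.89 ± 0.18). Hypoxia-responsive genes rose in 3 of 14 (4 adjusted over the list alone), including P4ha1 (0.47 ± 0.11) and Pfkfb3 (0.37 ± 0.09). Adjusted p was 5.55e-17, 3.62e-13 and 0.0211 for these 3 lists, and adjusted p = 0.0535 with an estimated correlation for each of them.

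Glial and metabolic lists shifted in prl sections with few single calls. Microglia genes rose in 3 of 15 (3 adjusted over the list alone), with Cd68, a lysosomal protein, at 0.44 ± 0.10 and Aif1 at 0.52 ± 0.13 (list adjusted p = 9.45e-07; adjusted p = 0.344 with an estimated correlation). Reactive astrocyte genes rose in 2 of 14 (6 adjusted over the list alone; list adjusted p = 0.000599; adjusted p = 0.344 with an estimated correlation). The 2 were Gfap (0.85 ± 0.24) and Vim (0.62 ± 0.18), filament proteins. Gfap lost its call without prl control 1, 2, 3, 4 or 9 or prl test 9 or 10 (adjusted p up to 0.0821). Vim kept its call only without prl control 10 or prl test 1, 4, 13 or 14, and lost it in the 13 other fits that left out 1 section (up to 0.102). Paired by number, neither Gfap (adjusted p = 0.062, edgeR) nor Vim (0.0603) was called. Glycolysis genes (0 of 14, 5 adjusted over the list alone) and synaptic vesicle genes (0 of 17, 0 adjusted over the list alone) shifted up as lists, with adjusted p = 0.000976 and 0.00116 but adjusted p = 0.455 and 0.502 with an estimated correlation. Interferon-response genes shifted down (adjusted p = 0.0156; adjusted p = 0.950 with an estimated correlation), with 1 of 19 falling (1 adjusted over the list alone), the signal transducer Stat2 (-0.21 ± 0.05). Erythrocyte genes (adjusted p = 0.0649), Y-linked genes (0.695) and mitochondrial genes (0.919; median change 0.02, direction of the test down) did not pass as lists.

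In all, edgeR called 468 genes up and 429 down in whole prl sections, 897 of 17623 tested. Among the 10 ways of parting the 6 runs 3 against 3, 4 others called more genes than the real one (3274, 2071, 2015 and 1061). Summed by run, edgeR called 0 genes (654 at unadjusted p under 0.05), and limma-voom with the run as a random block called 10 (9 up, 1 down). The p-values of the main fit therefore measure differences between sections, not between runs, each of which may be 1 animal. The count was 355 within sections with CA1 (247 up, 108 down) and 30 within those without (24 up, 6 down), and fell to 499 without prl control 3, 520 without prl control 1, 585 without prl test 9 and 585 without prl test 10. Among the named genes, Fosb, Egr4, Fos, Egr1 and Rgs2 were still called with the random block.

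**Figure D2:**
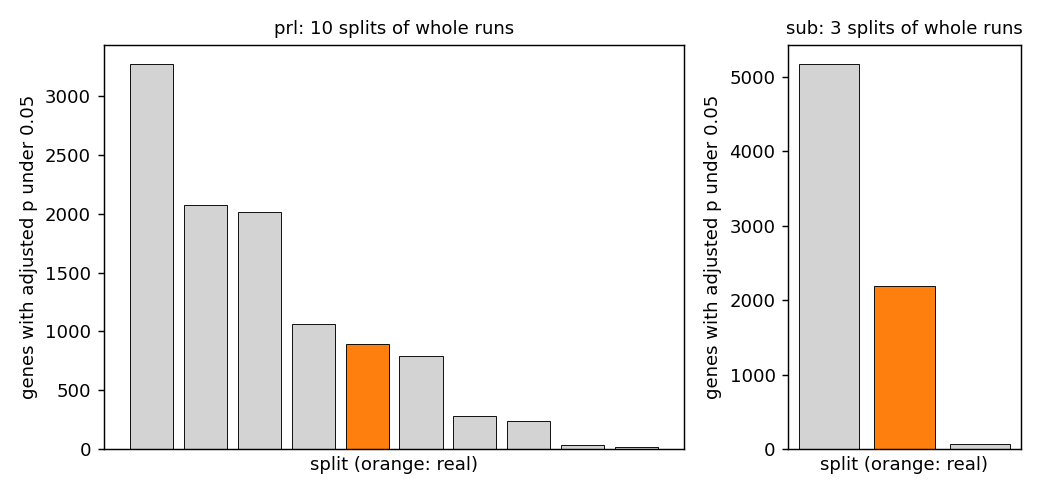
Genes called in whole sections (bars; vertical axis, number of genes at adjusted p under 0.05) for every way of parting the runs of a set into 2 equally large groups. The orange bar is the real parting into control and test. In the prl set 4 partings exceed the real 897, and in the sub set 1 of the other partings calls 5175 genes against the real 2191. That parting follows sex and section numbers alike.

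In whole sub sections, too, transcription factors that follow neuronal firing rose. Fosb rose from 9.74 ± 2.63 CPM (SD, n = 6) to 295 ± 160 CPM (SD, n = 8), a log2 change of 4.91 ± 0.56 (SE), Npas4 rose by 4.96 ± 0.77, Fos by 3.81 ± 0.46 and Egr1 by 2.80 ± 0.28. Egr4 (4.43 ± 0.52), Egr2 (4.11 ± 0.60), Atf3 (4.06 ± 0.82), Egr3 (3.60 ± 0.41), Ptgs2 (3.26 ± 0.68), Cenpa (3.28 ± 0.68), Homer1 (3.03 ± 0.36), Junb (2.21 ± 0.44) and Nr4a1 (1.92 ± 0.42) rose too. So did Rrad, a GTPase that restrains calcium channels (3.07 ± 0.46). Every gene named so far for this set was above every control section in 8 of 8 test sections. Arc rose by 2.64 ± 0.55 and Bdnf by 1.49 ± 0.43, with adjusted p = 0.0916 and 0.0536 when sections were paired by number, and were above every control section in 8 and 4 of 8 test sections.

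Among falling genes of sub sections, Rasl10a, a small GTPase, fell by 1.59 ± 0.30 on the log2 scale, from 39.9 to 13.3 CPM, and Npy2r, a receptor for neuropeptide Y, fell by 1.02 ± 0.24. Pwwp2b fell by 0.78 ± 0.16, Elk1, a transcription factor that acts on early response genes, by 0.73 ± 0.14, and Ccdc71l by 0.72 ± 0.14. Lhx9, a homeodomain factor, fell by 0.69 ± 0.11, Traip by 0.68 ± 0.16 and Amer3 by 0.60 ± 0.14. Lhx9, Ccdc71l and Amer3 were below every control section in 8 of 8 test sections, Npy2r and Traip in 7, Rasl10a and Elk1 in 4 and Pwwp2b in 3. Lrrc10b (-0.67 ± 0.18) and Otub2 (-0.63 ± 0.17) were called with all sections and were below every control section in 4 and 6 of 8 test sections. Lrrc10b lost its call without sub control 5 and without sub control 6 (adjusted p up to 0.0781) and when sections were paired (0.107). Otub2 lost it without sub control 6 (adjusted p = 0.0516).

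In the gene groups of sub sections, 22 of 26 rapid and 22 of 24 delayed activity-regulated genes rose (25 and 22 adjusted over the list alone). Among the delayed genes were Rgs2 (1.73 ± 0.21), Pim1, a kinase (2.40), and Per1, a clock gene (1.25). Adjusted p was 2.17e-30 and 2.63e-24, and adjusted p = 0.0572 and 0.0441 with an estimated correlation. Hypoxia-responsive genes rose in 5 of 14 (6 adjusted over the list alone), including Pfkfb3 (0.54 ± 0.10) and Egln3 (0.48 ± 0.12), with adjusted p = 0.00516 and adjusted p = 0.0441 with an estimated correlation. Cholesterol synthesis genes rose in 9 of 17 (10 adjusted over the list alone), including Cyp51 (0.86 ± 0.12), with adjusted p = 1.01e-06 and adjusted p = 0.413 with an estimated correlation. Heat shock genes rose in 5 of 20 (6 adjusted over the list alone), including Dnajb5 (1.12 ± 0.20) and Hspb1 (1.04 ± 0.21). Their adjusted p was 0.00216, then adjusted p = 0.413 with an estimated correlation and 0.136 when sections were paired. Glucocorticoid-responsive genes rose in 4 of 15 (6 adjusted over the list alone), with Klf9, a zinc finger factor, at 0.36 ± 0.06 and Errfi1, an inhibitor of growth factor receptors, at 1.55 ± 0.33 (adjusted p = 9.62e-05; adjusted p = 0.413 with an estimated correlation). Circadian genes rose in 6 of 16 (8 adjusted over the list alone), including Per1 and Bhlhe40 (0.63 ± 0.08), with adjusted p = 0.0488, adjusted p = 0.413 with an estimated correlation and 0.256 when paired.

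Some lists of glia and vessel genes shifted up in sub test sections. Microglia genes rose in 9 of 15 (13 adjusted over the list alone), with Trem2, a lipid receptor, at 0.61 ± 0.12 and Cd68 at 0.52 ± 0.11 (adjusted p = 4.08e-08; adjusted p = 0.258 with an estimated correlation). Cd68 was above every control section in 8 of 8 test sections, Trem2 in 6, and the complement genes C1qb and C1qc in only 3. Spots of the Ccl5/Ccl4 region, led by chemokine genes, made up 4.82% of sub test 5 and 3.70% of sub test 6 but at most 0.242% of any other section, and no list was tested without both of these. Reactive astrocyte genes rose in 6 of 14 (9 adjusted over the list alone), with Emp1, a membrane protein, at 1.36 and Osmr, a cytokine receptor, at 0.78 ± 0.19 (adjusted p = 9.62e-05; adjusted p = 0.265 with an estimated correlation). Of the other rising members, Vim (0.71 ± 0.21) lost its call without sub test 5 or 6 (adjusted p up to 0.0644). Lcn2, a secreted lipocalin (2.05 ± 0.62), lost it without sub control 5, 6, 7 or 8 or sub test 5 or 6 (up to 0.115) and when sections were paired (0.0563), and was above every control section in only 2 of 8 test sections. Mural cell genes rose in 4 of 11 (6 adjusted over the list alone), with the contractile genes Acta2 at 0.55 ± 0.11 and Cnn1 at 1.17 ± 0.23 (adjusted p = 0.000155; adjusted p = 0.258 with an estimated correlation). Choroid plexus genes (0 of 11, 0 adjusted over the list alone) and astrocyte genes (0 of 14, 0 adjusted over the list alone) shifted up as lists with adjusted p = 0.0154 and 0.0477, but adjusted p = 0.734 and 0.750 with an estimated correlation, and 0.110 for astrocyte genes when paired. Endothelial genes rose in 3 and fell in 1 of 11 (4 adjusted over the list alone; list adjusted p = 0.535). Meningeal fibroblast genes rose in 0 and fell in 3 of 12 (4 adjusted over the list alone; list adjusted p = 0.535), and myelin genes rose in 0 of 14 (0 adjusted over the list alone; list adjusted p = 0.0816). Erythrocyte (adjusted p = 0.535), mitochondrial (0.537) and Y-linked genes (0.566) did not pass as lists.

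In all, edgeR called 1062 genes up and 1129 down in whole sub sections, 2191 of 17623. The 4 runs can be parted 2 against 2 in 3 ways. The parting of male sections 5 to 8 of both groups from the female sections with higher numbers called 5175 genes, and the remaining one 64. Sex cannot be told apart there from anything else that differs between those numbers. Summed by run, edgeR called 2 genes, both down (1543 at unadjusted p under 0.05), limma-voom with the run as a random block called 274 (192 up, 82 down), and within sections without CA1 the count was 655 (383 up, 272 down). Among the named genes still called with the random block were Npas4, Fosb, Egr4, Egr2, Fos, Egr3, Rrad, Lhx9, Egr1, Arc, Homer1, Rgs2, Per1, Pim1, Cyp51 and Emp1.

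Set against each other, the 2 sets shared 335 rising genes, where 28.2 would be shared if the calls were independent, and 238 falling genes (27.5). No section served in both comparisons. Both came from 1 fit, however, which filters genes and estimates each gene's spread once, so calls could be shared for that reason too. The changes of single activity genes were not shown to differ between the sets. By estimate they were larger in sub sections for Fos (0.95 ± 0.53; adjusted p = 0.548), Egr1 (0.91 ± 0.33; adjusted p = 0.319) and Homer1 (0.93 ± 0.43; adjusted p = 0.458). By estimate they were smaller for Bdnf (-0.32 ± 0.55; adjusted p = 0.881), Ptgs2 (-0.74 ± 0.82; adjusted p = 0.800) and Atf3 (-0.73 ± 0.99; adjusted p = 0.849). The effect differed for 6 genes, 3 in each direction, a count that was 74 with DESeq2, 141 with limma-voom, 692 with region composition as covariates and 102 within sections with CA1. Cirbp, a cold-induced RNA-binding protein, went from 111 to 101 CPM in prl and from 103 to 136 CPM in sub sections, a difference of 0.54 ± 0.10 (adjusted p = 0.0404). Pik3cd, a subunit of a phosphoinositide kinase, went from 15.1 to 15.4 CPM in prl and from 15.2 to 11.4 CPM in sub sections, a difference of -0.44 ± 0.07 (adjusted p = 0.0223). Leaving out 1 section ended the call of Cirbp in 16 of 32 fits (adjusted p up to 0.0935, without sub control 5) and that of Pik3cd without prl control 4, sub control 6, 7 or 8 or sub test 7 (up to 0.0647). The 4 others, Otoa, Slc38a5, Gm47270 and 9630013A20Rik, fall outside the naming rule and were picked out after their values were seen. The count itself moved with single sections. It was 0 in edgeR without prl control 4, sub control 6, 7 or 8 or sub test 7 (1317 to 1870 at unadjusted p under 0.05; no other tool was run there) and 1 to 3 without prl control 1, 3 or 10, prl test 9, sub control 5 or sub test 6 or 8. It was 10 without prl control 13, 11 without prl control 9, 12 without sub test 5, 16 without prl test 14 and 36 without sub control 12. Summing by run gave 0 genes in edgeR (427 at unadjusted p under 0.05) and 0 in limma-voom with the run as a random block (279 at unadjusted p under 0.05).

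Within regions, firing-related genes rose strongly in spots with dentate gyrus markers, the hippocampal entry layer of granule cells. In the C1ql2/Ddn region of prl sections (8 control, 10 test), Fosb rose from 7.94 to 335 CPM (6.02 ± 0.85 on the log2 scale), Atf3 by 7.08 ± 1.09, Ptgs2 by 5.43 ± 0.78 and Npas4 by 5.37 ± 0.98, and Amer3 fell by 1.26 ± 0.19. With at least 50 spots per section the calls of Atf3 (adjusted p = 0.0570, edgeR), Npas4 (0.108) and Amer3 (0.0555) were lost, at similar estimates. In the same region of sub sections (6 control, 8 test), Homer1 rose from 33.4 to 1040 CPM (4.92 ± 0.21), Npas4 by 5.56 ± 0.25, Fosb by 4.93 ± 0.42 and Pim1 by 4.75 ± 0.32. Kcng1, a potassium channel subunit, fell there by 2.58 ± 0.27, Tnfrsf25, a receptor of the TNF family, by 2.11 ± 0.29, and Islr2 by 1.85 ± 0.24. The 2 sets were not tested against each other within regions.

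Firing-related genes were also higher in test sections in regions with other markers. The Trbc2/Myl4 region was led by the cortical layer 6b set of 3 markers (mean log2 fold 2.10 in control spots), with the layer 6 set next (1.41). Its 5866 spots therefore need not be layer 6b alone. Fosb rose there by 3.23 ± 0.35 in prl and 5.39 ± 0.33 in sub sections, and Pwwp2b fell by 0.91 ± 0.16 and 1.63 ± 0.25. The Hcrt/Pmch region, with hypothalamic markers, showed Egr3 higher by 3.58 ± 0.49 in prl and 4.74 ± 0.27 in sub sections, and Rsrp1 lower in prl sections (-0.38 ± 0.06). In the Gbx2/Ramp3 region, with thalamic markers, Npas4 rose by 3.74 ± 0.56 and 4.52 ± 0.18, Slitrk6, a neurite-controlling membrane protein, fell by 0.52 ± 0.09 in prl sections and Vash2 by 0.67 ± 0.12 in sub sections. In the Lefty1/Spink8 region, with CA1 markers, Htr1a, a serotonin receptor, fell by 0.82 ± 0.13 in prl sections (4 control, 5 test), and Npas4 rose by 5.67 ± 0.24 and Fos by 4.67 ± 0.40 in sub sections (4 control, 4 test). Fosb was among the named rising genes in 20 of 27 prl and 25 of 26 sub regions.

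Rapid activity-regulated genes as a sum were higher in test sections in 27 of 27 prl regions, by at least 0.42 on the log2 scale (Ttr/Ecrg4, choroid plexus markers), and by 1.95 in the C1ql2/Ddn region. In 24 of these the exact permutation test passed after adjustment. The Lefty1/Spink8 region (adjusted p = 0.0952, exact permutation), the Agrp/Oxt region (0.0683) and the Slc5a7/Slc10a4 region (0.0683) did not pass. In sub sections the sum was higher in 26 of 26 regions, by at least 0.74 (Ttr/Ecrg4) and by 2.37 in the C1ql2/Ddn region, and passed in 26. These permutations count sections as independent, although sections of a run were correlated by 0.44 (0.564 with the level in the model). No region's sum was tested by run, and the regions of a set come from the same sections.

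Counted over gene-region pairs, edgeR called 1797 up and 341 down in prl (2138 pairs in 27 regions) and 4795 up and 1701 down in sub sections (6496 pairs in 26 regions). The C1ql2/Ddn region held 265 rising and 41 falling genes in prl and 497 and 260 in sub sections, and the Trbc2/Myl4 region 161 and 44 in prl and 411 and 172 in sub sections. Summed by run, edgeR called 0 prl pairs (13837 at unadjusted p under 0.05; no other tool was run on these sums) and 493 sub pairs (481 up, 12 down), of which 465 were also called with sections and 262 were genes of the activity lists. Of the falls named for sub regions, Kcng1 was among the 12 (adjusted p = 0.0491), and Tnfrsf25, Islr2, Pwwp2b and Vash2 were not. Paired by number, the sub count was 9996. Leaving out 1 section moved the prl count to between 871 and 5481 and the sub count to between 4231 and 6652. The prl count was 871 without prl control 2, 957 without prl control 1, 1159 without prl control 4, 1336 without prl control 9, 1396 without prl control 13, 1198, 1170, 1332 and 1393 without prl test 1, 2, 3 and 4, and 5481 without prl test 13. The sub count was 4231 without sub control 6 and 4325 without sub control 5.

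Shares of spots per region did not pass the exact permutation test: 0 of 39 in prl sections (0 at unadjusted p under 0.05; lowest adjusted p = 0.978) and 0 of 38 in sub sections (2 at unadjusted p under 0.05; lowest adjusted p = 0.519). No other tool was run on these shares, and the correction over sections can itself even them out. Rasl10a, a leading gene of the C1ql2/Ddn region, was lower there in sub test sections (-2.34 ± 0.42; not called with at least 50 spots per section), so the share of spots assigned to it can depend on the response itself.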

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

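Anatomy and depth as covariates were planned, but the share of calls by which these tests were judged was chosen only after the counts of changed genes had been seen, and so were sex as a covariate, sums by run, the run as a random block, the naming of single sections and the splits that part all sub pairs, while the random splits and the splits that keep runs whole had their outcomes stated beforehand.

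The counts of called genes were the first pattern weighed: how far they stand for activation, and how far for differences between animals, anatomy or depth. Set against random splits of single sections, 2 of 100 splits of the prl sections called as many genes as the real 897, the real one included (highest other 982), 2 of 100 did for the real 2191 of sub sections (highest other 3133), and 1 of 100 did for the real 6 of the difference (highest other 0), so chance can be excluded for all 3 only if sections count as independent. For pairs of gene and region, 1 of 25 splits was as large as the real 2138 in prl (highest other 98) and 1 of 25 as the real 6496 in sub sections (highest other 4), the real one in each case, so chance can be excluded under the same condition. Sections of a run were correlated by 0.44 (0.564 with the level in the model), so the condition does not hold and these splits do not exclude differences between runs. Summed by run, edgeR called 0 genes of the difference (427 at unadjusted p under 0.05; 0 in limma-voom with the run as a random block, 279 at unadjusted p under 0.05). It called 0 prl pairs (13837 at unadjusted p under 0.05; no other tool was run on these sums) and 493 sub pairs (481 up, 12 down). Among splits that part all 4 sub pairs, 240 in all and 100 drawn, the real 2191 was the largest (highest other 874). Most of these splits break runs that the real one keeps whole, so they do not bear on differences between runs. The high counts of some other splits point to a structure of the samples, and the splits that keep runs whole show it.

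Differences between runs, each of which may be 1 animal, stay open as a cause of many whole-section calls. In the prl set 4 of the other splits that keep runs whole exceeded the real one, the highest (3274) setting control sections 1 to 4 and 9 to 10 with test sections 1 to 4 against the rest. In the sub set 1 did (5175), the split of male sections 5 to 8 of both groups from the female sections with higher numbers. Sex and number go together there, so these calls cannot be credited to sex. The real count was 2735 with sex as a covariate, which in this set also parts those numbers. The tables argue against depth as the whole cause: with it as covariate 99.4% of the called prl genes and 97.3% of the called sub genes were still called. With region composition as covariates 95.4% and 94.5% were. This does not rule anatomy out, since only the main components of region shares entered, and the correction over sections can even these shares out. Calls also differed by level, 355 with and 30 without CA1 in prl sections. Over all genes tested, run means of test and control did not overlap for 8.32% in prl (10% by chance) and 32.2% in sub sections (33.3% by chance). Activation, which the design names, stays open beside the runs.

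Egr1 in prl control 10 stood apart from its group at 159.8 CPM. By the same measure 3 sections were picked out in added features, within what counting alone gives, since a count of 0 allows up to 3 UMIs. Con1 had 1 UMI in prl control 1 and 1 UMI in prl test 14, where the rest of those groups had 0, and Con2 had 2 UMIs in prl test 11, where the others had 0 or 1. In 64 groups of values looked through this way 4 had such a section, 3 of them on 1 or 2 UMIs. How many chance alone would give was not tested.

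The change differed between the sets, by the test of the difference itself, for 6 genes. It was more positive in sub sections for Otoa (2.30 on the log2 scale), 9630013A20Rik (1.71) and Cirbp (0.54), and more negative for Slc38a5 (-1.86), Gm47270 (-1.80) and Pik3cd (-0.44). Cirbp lost its call without prl control 1, 3, 4 or 10, prl test 1, 4, 9, 10 or 11, sub control 5, 6, 7 or 8 or sub test 6, 7 or 8 (adjusted p up to 0.0935), and Pik3cd without prl control 4, sub control 6, 7 or 8 or sub test 7 (up to 0.0647).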

How the results depend on the processing

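Fits by level, sex, CA1 sections, runs (summed, averaged or as a random block), numbered pairs without the block, uncorrected regions and the robust fit were chosen only after the data had been seen. The cause of a changed count was not tested unless stated.

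Counts of changed genes kept within 1.5 times their value under the other alternatives, and moved as follows. In prl sections (897) limma-voom with quality weights gave 2024, region composition as covariates 1371 and the block for numbers 1529. Sections with CA1 gave 355 and those without gave 30, sums per run 0 and the random block 10. Omission of 1 section gave 499 to 1309. Each prl group held as many sections with CA1 as without, so the number of sections does not explain 355 against 30. In sub sections (2191) limma-voom gave 3310, composition 3945, sections without CA1 655 (2667 in as many sections with CA1), sums per run 2 and the random block 274. For the difference (6) DESeq2 gave 74, limma-voom 141, composition 692, depth 12, 1 surrogate variable 11, level 37, sex 42, sections with CA1 102 and without 2, sums per run 0 and the random block 0, and omission of 1 section 0 to 36.

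Gene-region pairs in prl sections (2138) numbered 964 with 50 spots, 3882 with DESeq2, 1276 with finer regions, 774 without the correction over sections and 0 summed by run, and 871 to 5481 without 1 section. In sub sections (6496) they numbered 4199 with 50 spots, 9996 with the block, 4048 with finer regions, 2518 without the correction and 493 summed by run, and 4231 to 6652 without 1 section. With an estimated correlation 0 of 10 prl and 2 of 12 sub lists were called. The rapid activity sum kept its direction but not its call averaged over runs (1.08 in prl, 2.20 in sub sections) and in sub pairs (1.80), where the designs allow no p under 0.05. Shares and depth passed under no alternative.

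Of the 132 calls of named genes in whole sections, 132 stood with DESeq2, 126 with limma-voom, 127 without a filter, 129 with composition, 42 in sections without CA1, 31 with the random block and 0 summed by run. With the block, 103 stood and 27 weakened, and it was not run for Cirbp and Pik3cd. Under the other settings the rest weakened, except Grm2, which reversed in sub sections without CA1 (0.036 against -0.43). Leaving out 1 section kept 1927 and weakened 169 such calls, and in regions kept 8845 and weakened 1624. The simulations, which left out the spread particular to single genes, limit what can be seen: 1.5-fold changes were found for 64.2% of genes in prl and 52.2% in sub sections.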

Other observations

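Tests of the viral feature, of the immune region and of a link between viral and activity transcripts were all chosen only after the results had been seen.

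Single receptor, channel and vessel genes were called in lists that did not pass, in both directions. In sub sections Kcna1, a potassium channel of axons, rose by 0.75 ± 0.17 on the log2 scale, and Htr2a, a serotonin receptor, by 0.70 ± 0.16 (above every control section in 5 and 7 of 8 test sections). Kcnd2, of the same channel list as Kcna1 (1 of 18 rose and 1 fell), fell by 0.19 ± 0.05, a call lost without sub control 12 (adjusted p = 0.053), when sections were paired by number (0.0876), with limma-voom (0.147) and in a fit of the sub set alone. Grm7, a presynaptic glutamate receptor, fell by 0.44 ± 0.08 and was below every control section in 8 of 8 test sections, within a glutamate receptor list in which 3 of 19 fell (list adjusted p = 0.0737). In prl sections Slco1a4, an endothelial transporter, fell by 0.30 ± 0.06, Pdgfrb, a pericyte receptor, by 0.26 ± 0.06, and Slc6a13, a transporter of the meninges, by 0.67 ± 0.16 (below every control section in 9, 8 and 8 of 10 test sections). Esam, of the same endothelial list as Slco1a4 (1 of 11 rose and 1 fell), rose by 0.26 ± 0.07. Its call was lost without prl control 1, 2, 3, 9 or 14 or prl test 1, 2, 3, 4, 11 or 12 (adjusted p up to 0.0955) and when sections were paired by number (0.0772). The endothelial (adjusted p = 0.775), mural cell (0.695) and meningeal fibroblast lists (0.4003) did not pass in this set.

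Of the added features, VIRUS was found mainly in the sub set. It had 118209 UMIs in sub control 5, 123673 in sub control 6, 26741 in sub control 11, 802 in sub control 12, 202 in sub control 7 and 142 in sub control 8. Among sub test sections it had 13043 UMIs in section 5, 10380 in section 6, 3321 in section 15, 3650 in section 16, 136 in section 17, 128 in section 18, 65 in section 8 and 37 in section 7. In prl sections it had 0 to 33 UMIs. Con1 had 2088, 1751 and 304 UMIs in sub control 5, 6 and 11 and at most 11 elsewhere. EGFP had 0 UMIs in prl test 9, 10, 11 and 12, 4 to 16 in the other prl sections, 8 to 16 in sub control and 11 to 32 in sub test sections. cas9, GFP, mCherry and Chr2 had 0 UMIs in 32 of 32 sections, which allows up to 3 UMIs in each.

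In sections with CA1, mean VIRUS CPM was 10.6 times as high in sub control as in sub test sections. The values argue against deeper sequencing of the controls, since shares of UMIs were compared, which a deeper section does not raise by itself. Whether 1 run of controls carries the difference cannot be told apart: without sub control 5 and 6 the ratio was 5.08, but it then rests on sub control 11 alone. No biological explanation was tested.

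One region, Ccl5/Ccl4, lay almost wholly in 2 sections of 1 run: 190 of its 376 spots were in sub test 5 (4.82% of that section) and 154 in sub test 6 (3.70%). It was too rare elsewhere to be tested, and its name rests on only 7 control spots. Its leading genes were chemokine and interferon-induced ones, among them Ccl5, Ccl4, Cxcl10 and Isg15, so their level there follows from how the region was found. A viral UMI was present in 94.7% of the region's spots in sub test 5 against 11.7% of other spots, and in 96.8% against 10.7% in sub test 6.

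For this region a response around spots that hold the viral feature is a candidate explanation, since such spots were 8.13 and 9.04 times as frequent in it as outside. Blood as the source is argued against: the erythrocyte list was shifted by 0.25 and -1.59 on the log2 scale, region against other spots. Sub control 5 had the viral feature in 1956 of 3572 spots and held 0 spots of the region. Con1 had 2088 UMIs there but 1 UMI each in sub test 5 and 6, so the added sequences may differ between these sections. Sub test 15 and 16 had the viral feature in 262 and 271 spots and held 5 and 7 spots of the region. Whether the viral feature suffices by itself cannot be told from these values. Both sections may come from 1 animal, and a difference between animals or an injury to the tissue was not tested.

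A hypothesis was that spots with more viral UMIs hold more rapid activity transcripts in the regions with dentate gyrus and CA1 markers. The rank correlation within section was above 0 in 5 of 7 sections: 0.794 in sub control 5, 0.845 in sub control 6, 0.102 in sub control 11, 0.0702 in sub test 15 and 0.0629 in sub test 16, against -0.12 in sub test 5 and -0.10 in sub test 6. The mixture of signs leaves the hypothesis undecided, and spots are not independent replicates.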
